A study of Mus musculus and Homo sapiens with 38 samples.

How the data were processed

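The series lists 38 samples, of which 12 are immunoprecipitated (IP) libraries with a processed file. In enhanced CLIP, RNA crosslinked to a protein is recovered with the protein and sequenced beside an input of the same lysate. 8 IP libraries came from HEK293A cells, a human embryonic kidney line, in 4 LIN28B expression conditions named X1 to X4 with 2 libraries each; the labels give no level or order for them. 4 came from V6.5 mouse embryonic stem cells, 2 without (replicates 1 and 5) and 2 with (replicates 3 and 7) a LIN28 sponge, in this field a transcript that carries decoy sites for a protein. The labels name Lin28A as the protein pulled down in the mouse cells, while the same text speaks of LIN28B binding. Per the labels, doxycycline at 10 ng/ml induced the LIN28B transgenes, the sponge and the controls, and samples were taken 24 to 36 hours later. 10 input samples are listed without a file of their own, 1 for each mouse condition and 8 for the human cells. The 16 samples of ribosome-bound and total RNA have no file of their own and were not analysed here. Nothing beyond the design text's words for biological replicates says that replicates came from separate cultures.

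The submitters' processing notes name cutadapt, STAR and the builds mm10 and hg19. The caller of the clusters is not given in the sources used here. For each interval of the mouse cluster files and of the 6 reproducible lists, the authors deposited a −log10 p, which stops at 400, and a log2 fold of IP over input, judged from the values since the files have no header. All listed peaks lay above 3 on both scales. The human cluster files deposited by the authors give a caller's p-value for the IP library alone and a name that ends in a whole number, which was read as the count of reads in the cluster. The human values are therefore not set against input, and they move with RNA level and with how much was called.

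Mouse intervals were assigned with bedtools 2.31.1 to the gene of the largest exonic overlap on the same strand, then to the gene body, in GENCODE M21, whose build is the one the notes call mm10. No human annotation or genome was at hand, so human genes are given only by the identifiers in the files, with at most 2 printed each way, and the gene lists could not be matched to human genes. Peaks of 1 strand that touched or overlapped were joined into sites. Lists were compared by overlap on the same strand of at least 1 base and by the Jaccard index, the shared bases divided by the bases in either list.

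The gene-level measure for mouse was fixed as reads from the cluster names; these names hold no reads, so the stated substitute was used, covered bases per gene scaled to the library's total. Human genes were measured as reads in clusters, scaled the same way to reads per M (RPM). Both were taken as log2 with a pseudocount of 1, in genes with at least 20 covered bases or 10 reads in 2 libraries, and fitted with limma 3.58.1 in R 4.3.3. The Benjamini-Hochberg threshold was an adjusted p of 0.05. In the human cells 1 fit of 8 libraries gave an F-test and 6 pairwise contrasts. Similarity of replicates was tested by an exact permutation test over all pairings of the 8 libraries, one-sided.

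16 gene lists were fixed: ribosomal proteins, translation factors, splicing and other RNA-binding proteins, oxidative phosphorylation, glycolysis, endoplasmic reticulum and secretion, membrane and secreted proteins, cell cycle, pluripotency, markers of differentiated and feeder cells, let-7 loci with their host genes, let-7 target mRNAs, microRNA machinery, insulin-like growth factor and mTOR signalling, abundant noncoding RNAs, and histones. Histones were left out because 4 of the 24 symbols matched, and 15 lists were tested. Genes with reproducible peaks were tested with Fisher's exact test, two-sided, against all genes with a cluster in both libraries of the condition, and the contrast with limma's camera at a preset correlation of 0.01 and with an estimated correlation. GGAG, the motif bound by the LIN28 zinc knuckles, was counted in the exonic part of sites and in windows of the same width shifted by 300 bases along the transcript, since transcript but no genome sequence was given. Apart from the omission of histones and the GGAG windows, these choices, the groups and the rule for named genes were written before the data were examined. For GGAG the plan called for a genome sequence, so the count in sites along transcripts was a later substitute.

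The rule named Lin28a and Lin28b first; the 10 genes each way with the largest change past the threshold, or the smallest p where fewer than 5 passed, as values; the 5 peaks of highest fold per list; and up to 4 members of each gene list with a peak in every condition. Other names were chosen after their values were seen: examples of members without a peak in the sponge list, genes at sites that passed a test, and genes with differing IP reads.

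Depth was recovered from the mouse files. The deposited log2 folds are ratios of whole reads to a common factor within a tolerance of 1e-08, and fold and p together gave the library totals. Among 1000 clusters per library not used to find the totals, 92.7% to 97.7% matched their p within 1e-07. With totals 10% lower 0% matched, and with totals 10% higher at most 5.8% did. IP totals were 13.4 and 14.2 M reads without and 15.5 and 9.17 M with the sponge. The recovered input totals were equal to 3 digits within a condition, 0.620 M (no sponge) and 0.556 M (sponge) reads, as if 1 input had served both libraries, although the design text names 2 inputs per condition. At identical cluster coordinates 75.9% of input counts were equal between the no-sponge libraries and 55.2% between the sponge libraries, against 6.10% to 8.96% between conditions. Between 86.8% and 92.0% of clusters rested on 1 input read, where a fold of 8 takes 132 to 223 IP reads. A count of 1 was the lowest that could be recovered, so it may also stand for no input reads. Intervals cover counting error only.

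Human depth is known only as reads in clusters, 1.41 to 4.41 M per library. On simulated data, changes of log2 1 and 2 were found for 63% and 100% of changed genes in the mouse covered bases. The shares were 50% and 97% in the mouse IP reads, and 18% and 97% in the human contrast of X4 with X1. Unchanged genes called numbered 12, 5 and 11 in turn. In the real covered bases, Dusp10 differed by −4.83 (SE 0.18) without passing (limma adjusted p 0.0603). The simulated shares therefore overstate what the mouse covered-bases fit could find.

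The alternatives were other pseudocounts, filters, scalings and variance models, stricter peaks, other overlaps, a replicate block and leaving out each library. Recovered IP and input reads, the authors' fold per gene and per site, sites picked on IP reads, counts without mitochondrial clusters and human reads per site were added after seeing the data. Tables and plots used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.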

Results

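Enhanced CLIP maps the RNA sites of LIN28, an RNA-binding protein that blocks maturation of the let-7 microRNAs and also binds many mRNAs. The samples cover mouse embryonic stem cells with and without a LIN28 sponge and HEK293A cells in 4 LIN28B expression conditions, with 2 IP libraries per condition and 12 in total. The mouse libraries without the sponge held 255905 and 243627 clusters, of which 1477 and 1069 passed both a log2 fold and a −log10 p of 3. Those with the sponge held 228319 and 163605 clusters, of which 406 and 320 passed. The human libraries held 68569 to 152564 clusters. With 2 libraries against 2, an exact permutation test cannot go below 0.333, so cluster numbers are given as values. Each reproducible list is 1 per condition and has no replicate error.

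The first question was which LIN28A sites in stem cells were still called when the sponge was expressed. Without the sponge, the peak with the highest fold lay in the 3′ untranslated region (UTR) of Eif4b, an initiation factor that aids the helicase unwinding mRNA (mm10 chromosome 15, 102095549 to 102095606, plus strand), at log2 6.22. Next came the 3′ UTR of Sox2, a core pluripotency transcription factor (chromosome 3, 34651894 to 34651981, plus strand), at 6.05. The coding region of Pabpc1, which binds poly(A) tails (chromosome 15, 36599243 to 36599350, minus strand), stood at 5.75. The coding region of Lin28a itself (chromosome 4, 134007957 to 134007998, minus strand) held adjoining peaks at 5.73 and 5.72. With the sponge, the highest folds lay in the coding regions of Eef2, the ribosome translocation factor (chromosome 10, plus strand, 5.41 and 5.30), and of Cdk4, a kinase of the G1 phase (chromosome 10, 5.05). The 3′ UTR of Srsf3, a splicing factor (chromosome 17, 4.84), and the coding region of Ran, a nuclear transport GTPase (chromosome 5, 4.82), followed.

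The no-sponge list held 1107 peaks in 663 sites and 340 genes, and the sponge list 185 peaks in 112 sites and 71 genes. 59 genes were in both, 281 in the no-sponge list alone and 12 in the sponge list alone. Of the no-sponge peaks 14.7% (95% Wilson interval 12.8% to 16.9%) overlapped a sponge peak. The interval treats peaks as independent, although the 1107 peaks join into 663 sites, so it is too narrow. Of the sponge peaks 77.3% overlapped a no-sponge peak. Many peaks lay in a few genes: Gm26917, annotated as a noncoding RNA, held 93 of the no-sponge and 15 of the sponge peaks. H19 held 39 and 24, and a further gene 28 and 23. The shares were not computed without these genes. The sponge libraries still had some cluster at 98.6% and 97.5% of the no-sponge peaks, but one past both thresholds at 26.7% and 15.0%. The libraries that defined that list had one at 94.9% and 89.1%. With an overlap of 50% of both peaks the share was 7.68%, and among peaks with a log2 fold of at least 4 it was 3.64%.

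**Figure D1:**
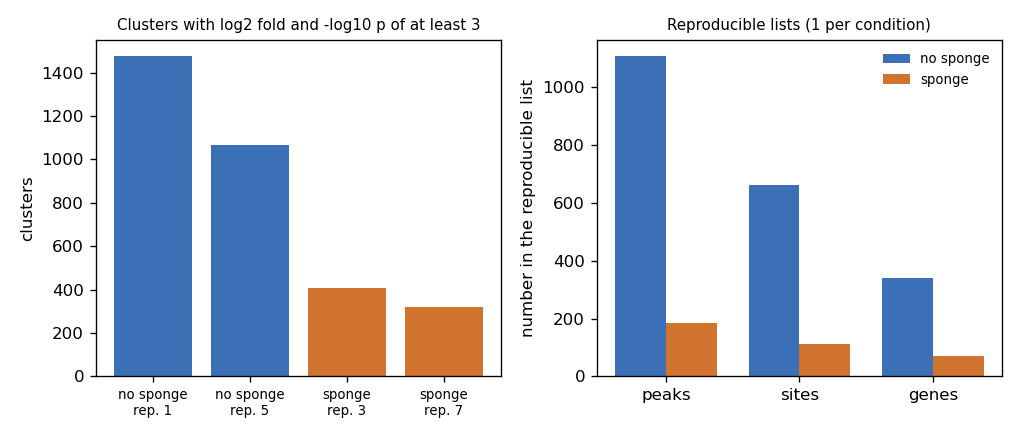
The left panel shows, per mouse library, the number of clusters with a log2 fold and a −log10 p of at least 3, and the right panel the numbers of peaks, joined sites and genes in the 1 reproducible list per condition. Bars are blue without and orange with the sponge, and clusters numbered 1477 and 1069 against 406 and 320.

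By gene group, the no-sponge list held 8 pluripotency genes, among them Sox2, Pou5f1 (a core pluripotency factor), L1td1 and Tet1 (a 5-methylcytosine oxidase), and the sponge list held none of the group. Ribosomal protein genes numbered 20 and 2, the latter Rps9 (6 peaks without and 2 with the sponge) and Rpl8 (18 and 3). Peaks here can be touching pieces of 1 site: the 3 Rpl8 peaks with the sponge lay in 1 site, and the 2 Rps9 peaks in 1. Peak numbers of a gene are therefore not numbers of separate sites. Translation factors numbered 13 and 1, the latter Eef2 (11 and 6). Genes of splicing and other RNA-binding proteins numbered 18 and 4, with Srsf3 (7 and 1), Hnrnpa2b1 (11 and 1) and Hnrnpab (7 and 4) in both lists and Hnrnpa1 in the sponge list alone. Membrane and secreted protein genes numbered 10 and 2, with the lysosomal Psap and the glucose transporter Slc2a1 in both. Endoplasmic reticulum genes numbered 9 and 3, with Ssr2, Canx and Spcs3 in both, and oxidative phosphorylation genes 8 and 2, with Atp5b (11 and 2 peaks) and Cox4i1. Cell cycle genes numbered 6 and 3, with Cdk4 (9 and 8) and Ccne1 in both and Plk1, a mitotic kinase, in the sponge list alone. Targets of let-7 numbered 4 and 2, with Igf2bp1 (5 and 1) and Mycn (3 and 1) in both. MicroRNA machinery genes numbered 4 and 1, with Ago2 in both. Abundant noncoding RNAs numbered 3 and 1, with the imprinted H19 (39 and 24) in both and Malat1 and Neat1 in the no-sponge list alone. Glycolysis genes numbered 3 and 0, and the let-7 loci group gave 2 and 0, the protein-coding hosts Huwe1 and Wdr82. Differentiated and feeder markers and insulin-like growth factor and mTOR genes had none in either list.

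Against all genes with clusters, 13 of the 15 groups were over-represented in the no-sponge list by Fisher's exact test. Ribosomal proteins gave an odds ratio of 12.8 (adjusted p 5.28e-13), splicing 13.5 (2.38e-12), pluripotency 12.7 (7.60e-06). Of translation factors in the background 36.1% had a peak, against 2.72% of all genes (adjusted p 4.71e-11). In the sponge list 5 groups passed: splicing with an odds ratio of 10.7 (adjusted p 0.00296), endoplasmic reticulum with 11.2 (0.00858), cell cycle with 10.7 (0.00884), let-7 targets with 13.3 (0.0212) and membrane and secreted proteins with 8.51 (0.0435). Peaks with a log2 fold of at least 4 gave 10 groups and 0 groups, and no test compared the groups between the lists. Abundant mRNAs gather more reads, and a background of genes with 50 reads gave 11 and 3 groups. A fold of 8 on 1 input read takes 132 to 223 IP reads, so genes with 50 reads can lie below reach of a peak. This background therefore does not remove the effect of abundance, and the odds ratios hold it. In the sponge list, let-7 targets (Fisher's exact test, adjusted p 0.0571) and membrane and secreted proteins (0.135) then no longer passed.

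At single sites of the no-sponge list, named after their values were seen, the authors' fold with the sponge differed by −3.61 at the Sox2 3′ UTR, −3.53 at a coding site of Pou5f1, −3.10 at the Lin28a coding site, −2.81 at the Eif4b 3′ UTR and −3.02 at the main Pabpc1 site. Sites were listed for a high fold in the same no-sponge libraries, which favours a lower fold in the others, so these are values and not tests. The fold rose at 2 sites, in the coding regions of Cdk4 (1.57, SE 0.53, adjusted p 0.00933) and of Ywhae, a 14-3-3 adaptor protein (1.13, SE 0.50, 0.0413), where IP reads differed by −0.33 and −0.64 and input reads by −1.91 and −1.79, so the higher fold went with fewer input reads. Of the 663 sites 646 had a cluster in all 4 libraries, and limma called the fold lower at 457 of them, a count that holds the same selection, with a median difference of −1.66 and 96.6% of sites lower. Sites were also picked for their fold in 1 library, and the libraries of the other condition were compared with its sibling. The sibling appears to share the input, so this comparison still holds a selection for few input reads. The median difference of the sponge libraries was −1.08 and −1.71 for picks in no-sponge replicate 1 and −1.48 and −2.07 for picks in replicate 5. For picks in sponge replicates 3 and 7, the no-sponge libraries differed from the sibling by 0.71 and 0.49 and by −0.04 and −0.19. No test set gene groups apart at sites. The median log2 fold was 3.74 and 3.46 without and 2.30 and 1.66 with the sponge. IP reads per M (RPM) at the same sites had a median change of −0.63, against −0.45 for IP reads of all genes. The gene values carried a pseudocount of 1, which shrinks the changes of weakly read genes, and the site values carried none. With at least 50 reads in 2 libraries the gene median was −0.48. Site and gene medians are therefore not on the same scale. IP reads passed at 0 sites in limma (102 at an unadjusted p under 0.05). Without no-sponge replicates 1 and 5 and sponge replicates 3 and 7 in turn, the site median was −0.51, −0.78, −0.91 and −0.33. The median of all genes was then −0.34, −0.58, −0.63 and −0.28. Clusters on coding and UTR sequence held 26.4% and 21.8% of IP reads without and 19.5% and 15.1% with the sponge. Clusters of all kinds held 44.1% and 39.8% without and 34.0% and 32.2% with it, and reads outside clusters were not assigned. Input RPM had a median change of 1.06, where a count of 1 may also stand for no reads. The libraries of a condition appear to share 1 input, with 75.9% and 55.2% of input counts equal at identical coordinates, although the design text names 2. With a shared input, the error of the fold leaves out the difference between inputs. Without sponge replicate 7, the library with the fewest IP reads, the median fold change was −1.38. Centred on each library's median, 64 sites were higher and 76 lower. Without no-sponge replicate 1 the fold was called lower at 254 sites and rose at 1, without no-sponge replicate 5 it rose at 0, and without sponge replicate 3 it rose at 3. IP reads fell at 355 sites without sponge replicate 3 (3 rose) and at 12 without sponge replicate 7 (6 rose).

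**Figure D2:**
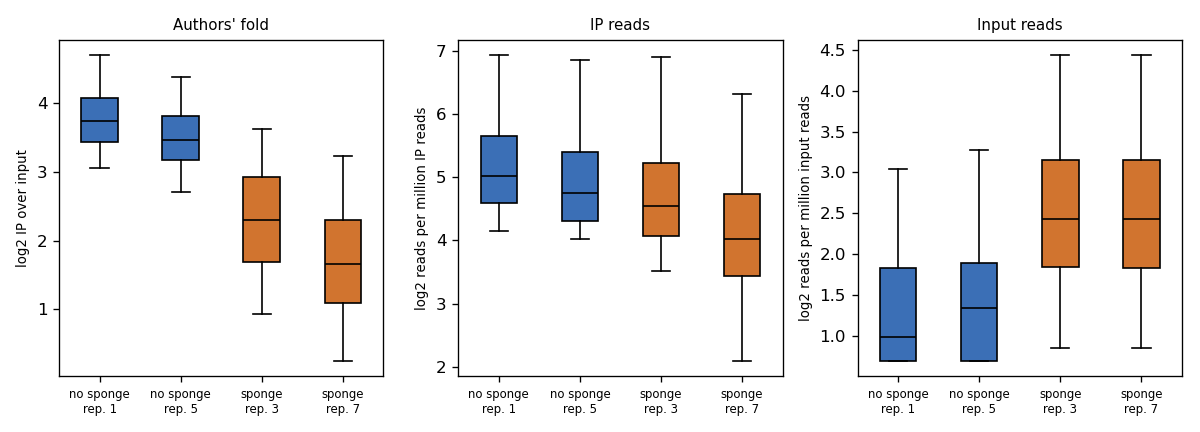
Boxes show, for 646 joined no-sponge sites in each mouse library, the authors' log2 fold, the log2 RPM of IP reads and the log2 RPM of input reads, with the median, the quartiles and whiskers from the 5th to the 95th percentile; axes do not start at 0. Median folds were 3.74 and 3.46 without and 2.30 and 1.66 with the sponge.

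Lin28a mRNA, which encodes the protein pulled down, had 202 and 194 IP RPM without the sponge and 110 and 79.0 with it. Its highest log2 fold was 5.68 and 5.77 against 3.22 and 1.96, and it had 3 reproducible peaks against 0. Lin28b, its paralog, had 25.8 and 18.6 against 20.6 and 13.2 IP RPM and no cluster past both thresholds. Neither passed gene by gene: Lin28a differed by −1.08 (SE 0.34, adjusted p 0.195) and Lin28b by −0.39 (SE 0.36, 0.465) in IP reads. Of 10 let-7 hairpins, 4 and 5 had a cluster without and 6 and 3 with the sponge. The highest log2 fold was at let-7d in each library, 2.67 and 2.33 against 2.70 and 1.35, and none reached a reproducible list.

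In covered bases per gene, the genes of smallest p were each listed at 0 in one condition. Dusp10, a phosphatase of stress kinases, had a mean log2 value of 4.83 without and 0 with the sponge. Krt19, an epithelial keratin, had 3.66 and 0, Snora2b 3.38 and 0, and Tal1, a blood transcription factor, 3.11 and 0. The opposite held for the pseudogene Rpsa-ps12 (0 and 3.76), the extracellular protease Adamts3 (0 and 3.58) and Fxyd5 (0 and 3.31). These are values, not changes: 0 of 13541 genes passed in limma, 891 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0603. Lin28a differed by 0.41 (SE 0.21, adjusted p 0.858). A pseudocount of 0.1 called 193 genes higher and 250 lower, and clusters with a −log10 p of at least 5 called 2 higher and 91 lower of 208.

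In IP reads, added after seeing the data, calls went both ways in several classes: 11 protein-coding genes were higher and 23 lower, small nuclear RNAs numbered 4 and 3, and small nucleolar RNAs 4 and 8 with 114 not called. Gm23287, annotated as a small nuclear RNA, fell by 4.24 (SE 0.39, adjusted p 2.76e-06), from 2587 and 1515 reads to 67 and 92. Rn7sk, which holds an elongation factor in check, fell by 3.62 (SE 0.64, 0.00543), from 5685 and 2264 reads to 1015 and 53. Rnu5g, a U5 spliceosomal RNA, fell by 3.06 (SE 0.37, 5.73e-05), and the modification guides Snord82 and Snord87 fell by 2.46 and 2.32. Rnu3b1, a U3 RNA of ribosome assembly, rose by 4.01 (SE 0.41, 6.49e-06), from 35 and 12 reads to 934 and 249. Gm26035 rose by 3.32 (SE 0.34, 6.49e-06), and Tmem26 was listed at 0 reads in both no-sponge libraries and at 330 and 265 with the sponge. Of 11315 genes 36 were higher and 42 lower in limma, against a median change of all genes of −0.45. Scaled to the median gene, 3 were higher (Tmem26, Gm26035 and Gm24812) and 0 lower, with 762 at an unadjusted p under 0.05. Small RNA genes have near-identical copies that share reads, so their values are uncertain. Higher and lower genes numbered 12 and 10 without no-sponge replicate 1, 11 and 21 without no-sponge replicate 5, 112 and 3626 without sponge replicate 3 and 33 and 124 without sponge replicate 7. With at least 50 reads they were 23 and 116.

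Ribosomal protein genes covered more bases with the sponge relative to other genes (camera adjusted p 2.09e-06, median log2 0.23), as did oxidative phosphorylation genes (3.68e-04, 0.24) and translation factors (3.68e-04, 0.22). Membrane and secreted proteins (0.00602, 0.18), endoplasmic reticulum (0.0115, 0.15), splicing (0.0172, 0.13) and pluripotency genes (0.0213, 0.17) also passed. Each of the 7 calls was lost with an estimated correlation (adjusted p from 0.678 to 0.682). The other 8 groups gave adjusted p from 0.0638 to 0.978 at the preset correlation, and the median of differentiated and feeder markers was 0.12 while their mean was −0.12. No member of a group passed over all genes or adjusted over the list alone. In IP reads, ribosomal proteins passed (1.65e-05), with a median of −0.23 against −0.45 for all genes, and had an adjusted p of 0.980 with an estimated correlation. In IP reads adjusted over the list alone, 2 abundant noncoding RNAs were lower (1 over all genes) and 1 oxidative phosphorylation gene was higher (0 over all genes).

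Coding regions held most sites in both mouse lists, 394 of 663 (59.4%) without and 59 of 112 (52.7%) with the sponge. 3′ UTRs held 196 (29.6%) and 21 (18.8%), exons of noncoding genes 48 and 18, introns 15 and 12 and 5′ UTRs 9 and 2. A few genes held most of the noncoding and intronic sites. Gm26917 (14 and 8 exon sites) and H19 (12 and 7), both annotated as noncoding RNAs, held most of the noncoding exon sites. Of the intronic sites, 1 gene held 13 of the 15 and 11 of the 12. GGAG stood in 48.9% of no-sponge sites with sequence and in 35.3% of shifted windows, an odds ratio of 1.76 (95% interval 1.44 to 2.15, Fisher's exact two-sided p 4.27e-08). By the ratio of the 2 shares, 1.39, it ranked 9 of the 256 motifs of that length, and 4 with windows shifted by 1000 bases. In sponge sites it stood in 35.5% against 29.5%, an odds ratio of 1.31 (0.765 to 2.25, p 0.333), and ranked 69 and 91. The difference between the lists was not tested, and their windows had a median of 74 and 54 bases. Sites and shifted windows were treated as independent, although each site shared a transcript with its windows and many sites shared a gene. The intervals and p of the GGAG counts do not allow for this.

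The second question was how LIN28B sites in HEK293A cells compared among the 4 expression conditions. The 5 peaks of highest fold in X1 lay on hg19 chromosome 11 between 17098715 and 17098740, minus strand (log2 9.79, 9.71 and 9.66), and on chromosome 19 between 49120034 and 49120077, minus strand (9.68 and 9.66). Those of X2 lay on chromosome 19 at 42373769 to 42373776, plus strand (8.90), chromosome 15 between 69071958 and 69072007, minus strand (8.83 and 8.76), chromosome 11 at 17098718 to 17098727, minus strand (8.70), and chromosome 17 at 73774431 to 73774440, minus strand (8.51). Those of X3 lay on chromosome 19 between 18417869 and 18417907, minus strand (8.28 and 8.23), and chromosome 1 between 46775884 and 46775940, plus strand (8.24, 7.94 and 7.79). Those of X4 lay on chromosome 3 between 127379786 and 127379806, plus strand (7.34 and 7.20), chromosome 11 between 17098761 and 17098767, minus strand (7.23 and 6.99), and chromosome 1 at 160248707 to 160248750, minus strand (7.22). The lists held 11692, 10475, 10334 and 10506 peaks from X1 to X4, in 4167, 3636, 3262 and 3243 genes. At the 4059 sites in all 4 lists the median log2 fold was 4.48, 4.27, 4.12 and 3.93, and X4 lay below X1 at 77.5% of sites, by a median of −0.59. These folds had no replicates and were not tested. Of 13680 joined sites 29.7% were in all 4 lists and 33.7% in 1. The Jaccard index of pairs of lists averaged 0.431 (0.374 to 0.502), and was 0.308 among peaks with a log2 fold of at least 4 and 0.702 for genes.

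On average, libraries of 1 human condition shared more covered bases than libraries of different conditions, though not every pair did. The Jaccard index averaged 0.368 over the 4 pairs of 1 condition and 0.344 over the 24 other pairs, and 2 of all pairings of the 8 libraries, the real one included, reached as high (exact one-sided p 0.0190). For genes with a cluster of at least 10 reads the exact p was 0.0952.

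**Figure D3:**
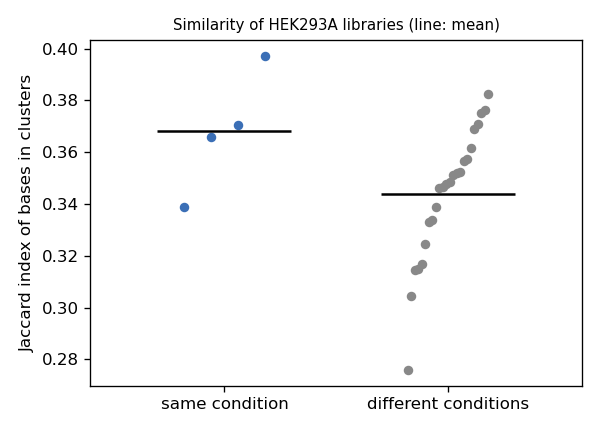
Each point is a pair of HEK293A libraries, placed by the Jaccard index of the bases in their clusters, blue for the same condition and grey for different conditions, with lines at the means; the axis does not start at 0. The means were 0.368 and 0.344, and the ranges of 0.339 to 0.397 and 0.276 to 0.383 overlapped.

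Gene by gene, reads in human clusters differed among the conditions for 63 of 11665 genes by limma's F-test (2345 at an unadjusted p under 0.05). Their conditions spanned a median log2 of 2.90. 21 of the genes were lowest in X1 and highest in X4, and 12 the opposite. The files do not pair identifiers with names, so LIN28A and LIN28B could not be looked up. ENSG00000175899.10 was listed with 156 and 207 reads in X4 and 0 in the other 6 libraries (F-test adjusted p 4.44e-04). ENSG00000090554.7 had 68 and 290 reads in X4, 3 and 3 in X3 and 0 in X1 and X2 (0.0109). ENSG00000257181.1 had 76 and 35 reads in X1, 16 and 10 in X2 and 0 in X3 and X4 (7.08e-04). ENSG00000135678.7 had 89 and 35 in X1, 24 and 16 in X2, 5 and 8 in X3 and 3 and 0 in X4 (0.0318). X4 against X1 gave 89 genes higher and 59 lower with a median change of 0.34, 62 and 107 when scaled to the median gene, 1092 and 309 with a pseudocount of 10, 1164 and 316 with a trended robust variance and 171 and 15 on covered bases. X3 against X1 gave 51 and 32, and 48 and 79 when so scaled, and the 6 contrasts summed to 299 calls. The 148 calls of X4 against X1 became 997 (897 higher and 100 lower) and 43 without X1 replicates 1 and 2, 74 and 73 without X3 replicates 1 and 2, 2 and 3 without X4 replicates 1 and 2, and 51 with a replicate block. The 83 calls of X3 against X1 became 1062 and 49 without X1 replicates 1 and 2, 15 and 13 without X3 replicates 1 and 2, 47 and 44 without X4 replicates 1 and 2, and 39 with a block. The F-test count was 457 without X1 replicate 1, 20 and 15 without X3 replicates 1 and 2, and 5 and 11 without X4 replicates 1 and 2. The sum over contrasts was 2446 and 178 without X1 replicates 1 and 2, 122 and 119 without X3 replicates 1 and 2, and 59 and 63 without X4 replicates 1 and 2. With a replicate block the F-test count was 27, and with a trended robust variance 1009.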

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

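Recovered reads, the authors' fold per gene or site, counts without mitochondrial clusters and human site counts were chosen after seeing the data; the other alternatives were planned. Where a value moved, the cause was not tested unless stated. A count was said to stay if its ratio to the reported count lay within a fixed limit. Other values stayed if they moved by less than their spread or interval, or kept their side of the threshold. Among counts and values answering a comparison, 37 alternatives stayed and 45 moved. A further 16 were counts that rose from 0, and 4 fell to 0 or no longer passed. Balances of higher and lower calls turned in several cases, among them these: IP reads by gene went from 36 and 42 to 12 and 10 without no-sponge replicate 1, X4 against X1 from 89 and 59 to 62 and 107 with median scaling and to 375 and 749 at sites, X3 against X1 from 51 and 32 to 48 and 79 with median scaling, and X4 against X2 from 23 and 6 to 42 and 71 with a pseudocount of 10. Among single contrasts, libraries and lists 69 stayed, 108 moved, 2 newly passed and 10 fell to 0 or no longer passed.

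The mouse count of 0 genes by covered bases was 443 with a pseudocount of 0.1 and 93 with clusters of −log10 p of at least 5, where fewer genes were tested. It was 78 on recovered IP reads, 3 with median scaling and 139 with at least 50 reads. On the authors' fold per gene it was 205 for the mean, 722 with 100 covered bases, 147 for the median, 891 for the highest fold and 220 in exons. Centred on each library's median these were 34, 0, 9, 134 and 14 (the 0 from limma, with 1109 at an unadjusted p under 0.05). Leaving out 1 library gave 0 for covered bases in each case (limma, 407 to 3118 at an unadjusted p under 0.05) and 22 to 3738 for IP reads; the lone library was assumed to vary like the other group.

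The human F-test count of 63 and the sum of 299 over contrasts were 893 and 2835 with a pseudocount of 10, 232 and 1483 with at least 50 reads, 251 and 804 on covered bases, 429 and 1763 with a caller p at or below 1e-05 and 1009 and 3130 with a trended robust variance. Reads at sites of the 4 lists gave 554. Leaving out 1 library gave 5 to 457 and 59 to 2446. With a replicate block they were 27 and 117. Whether the replicate numbers pair the libraries is not known. The gene residuals of replicates with the same number correlated from −0.04 to 0.094, which does not show pairing and cannot exclude it.

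Sponge clusters were 78.5% of no-sponge clusters, and 49.0% with a p at or below 1e-05. Sponge peaks were 16.7% of no-sponge peaks, 12.9% at a log2 fold of at least 4 and 10.0% at 5, and X3 peaks were 88.4% of X1 peaks, then 64.9% and 41.0%. The share of no-sponge peaks recovered, 14.7%, was 7.68% at an overlap of 50%, 3.64% at a fold of 4 and 17.4% by genes. The human Jaccard index of 0.431 was 0.308 at a fold of 4 and 0.702 by genes, and the mean share overlapped, 72.3%, was 55.9% at an overlap of 50%, 61.4% at a fold of 4 and 83.0% by genes. The exact p of 0.0190 for replicates was 0.0952 by genes and from 0.00952, the smallest possible, to 0.0190 in the others.

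The 18 list calls by Fisher's test were 10 at a fold of 4. The 7 camera calls were 0 with an estimated correlation, 1 on IP reads and 0 on IP reads with an estimated correlation (0 lists had an unadjusted p under 0.05 with either estimated correlation, and the smallest were 0.211 and 0.185). The 457 lower sites were 76 after centring, 254 to 524 without 1 library and 0 on IP reads (limma), which became 0 to 355 without 1 library, with 12 without sponge replicate 7. The human gene lists were not run, because no human gene names were given. Depth limits the mouse fold: over all clusters, at least 86.8% in each library rested on 1 input read, which may also stand for none.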

Other observations

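All tests in this part were chosen after the result was seen. Among RNAs with reproducible peaks in both mouse lists, H19, an imprinted noncoding RNA, had 39 peaks without and 24 with the sponge. At its 7 sites in the sponge list the authors' fold differed by −0.74 to 1.16, IP reads by 0.84 to 1.39 and input reads by 0.20 to 2.13 on the log2 scale, with no fold or IP difference past the threshold. Over the sponge list, whose sites were listed for a high fold in the sponge libraries, which favours a lower fold in the others, the fold rose at 8 of 111 sites and fell at 0 in limma (13 lower at an unadjusted p under 0.05), with a median change of −0.09. Of the 8, at Rnu3b1 and Gm26035 IP reads rose too, by 4.76 (adjusted p 0.0166) and 4.68 (0.00600), with input differing by 0.36 and 0.16. At Plk1, Hspa14 and Slc39a1, a zinc transporter, IP reads differed by −0.36, −0.15 and 0.09 and input reads by −1.80, −1.80 and −1.66, so the higher fold went with fewer input reads. At Dynll1 IP and input differed by 2.08 and −1.34, and at the 2 sites of Hnrnpa1, a splicing regulator, IP differed by 1.53 and 0.81 and input by 0.07 and −0.91. Without no-sponge replicates 1 and 5 the fold rose at 1 and 0 sites, and without sponge replicates 3 and 7 at 13 and 14, where it fell at 10 and 4.

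The lower authors' fold at no-sponge sites in the sponge libraries was weighed against its parts at sites picked on the IP reads of 1 library, with that library left out of the comparison; there the fold differed by −0.88, −1.24, −1.33 and −0.79. Picking of sites for few reads in the input that the no-sponge libraries appear to share cannot be told apart: sites with a fold of at least 8 in no-sponge replicate 5 gained 0.593 more log2 input reads with the sponge than all picked sites, but a high fold itself selects few reads in that input. More reads on expressed exons in the sponge input may contribute, since input RPM was higher at picked sites whichever library picked them. The smallest median change was 0.393. On this scale 1 read stands at 0.69 and 0.85 in the inputs, and it may also stand for none. With 1 input listed per mouse condition, a difference between input libraries and one between conditions are the same thing. Less LIN28A on its sites with the sponge, the biological hypothesis, cannot be told apart either. The change of IP reads with the sponge at sites of high fold, less that at sites of low fold, was −0.114. For the other picks it was −0.0956, −0.0986 and 0.0509. IP reads at all picked sites had median differences of −0.47, −0.73, −0.85 and −0.20. Over all genes, with the same library left out each time, the medians were −0.34, −0.58, −0.63 and −0.28. The libraries of a condition also differ from each other.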
